A study of Homo sapiens with 6 samples.

How the data were processed

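RNA-seq of the human acute myeloid leukaemia line MUTZ3 was analysed in 6 libraries, with 2 each of a PLDLS peptide construct, a PLASS peptide construct and an empty vector (EV). Per the labels, RNA was poly-A selected and libraries were not stranded, so reads of a gene and of an antisense partner cannot be told apart. Per the labels, EV replicate 1 and replicate 2 carry different vectors, and both were kept in the EV group that their titles give. Read layout, annotation release and Salmon options are not given in the sources used here.

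Per the submitters' processing notes, the authors used bcl2fastq 1.8.4, Salmon 0.3.1 and the build hg38. The deposited estimated counts are reads assigned to each RefSeq transcript by Salmon, not normalized and not whole numbers, per the file headers. The deposited TPM values, 1000000 per library, only served as a check. The deposited effective transcript length was only an offset in an alternative fit.

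Each table held 69004 transcripts. Of these 68201 were named from a RefSeq table (assembly GRCh38.p14) and 404 from a GENCODE table, and 399 had no gene name. In all 99.4% were named, giving 27722 genes, and 1092 transcripts with a copy suffix were summed with their gene. Reads on transcripts with no gene name were 0.0670% to 0.0891% of a library and were left out of library sizes and tests. Depth was lowest in PLDLS replicate 2, so its low genes are least precise. Counts of the replicates of a group differed by a chi-square per gene of 18.4 for PLDLS, 35.9 for PLASS and 77.2 for EV, above sampling noise, so all counted as separate libraries.

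Gene sums of estimated counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and a term per group over all 6 libraries. This left 3 residual degrees of freedom and 14631 tested genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, standard errors are the log2 fold change over the root of F, and CPM values are TMM-scaled. Groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Tables were prepared with Python 3.11.15 and pandas 2.3.3.

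The fit without a block was the first choice, with the replicate number as a block as its alternative. Whether the numbers pair the libraries was decided before the calls of the fits were compared. Differences between the numbers correlated across 9719 genes at 0.724 between PLDLS and PLASS, 0.537 between PLDLS and EV and 0.608 between PLASS and EV. The deposited table names carry an experiment number equal to the replicate number, but no label says that it marks a shared day or batch. With 2 numbers the check rests on these 3 correlations, so the pairing is inferred from the data. The common biological coefficient of variation was 0.236 without the block and 0.130 with it, which left 2 residual degrees of freedom.

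Genes were named by a rule. For PLDLS vs PLASS it took the 12 with the largest difference each way among those past the threshold, with a mean of at least 2 CPM and no overlap between the groups, and for the other comparisons 6 each way. Where fewer than 5 passed it took the 5 each way with the smallest p. MECOM, CTBP1, CTBP2 and GATA2 were always given, with up to 4 members with the smallest p of each list described. Applying the rule to the fit with the block, and ranking list members by its p, was decided after seeing the data. Coordinates are those of GRCh38. Of 31 gene lists, the 30 with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry as alternatives.

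The tests were checked on simulated data with 100 changed genes per fold size among 14451. For PLDLS vs PLASS the fit without the block recovered 0% of 2-fold and 68% of 4-fold changes with 0 false calls, and the fit with the block 73% and 99% with 6. For PLDLS vs EV the shares were 3% and 76% without the block, with 0 false calls, and 78% and 98% with it, with 17. A simulated 1.5-fold rise of oxidative phosphorylation genes in PLDLS vs PLASS was called by camera with the preset correlation and missed with an estimated one (adjusted p = 0.989, or 0.262 with the block). In the libraries themselves that list did not pass (adjusted p = 0.230, or 0.145 with the block). The simulation did not test false calls from genes that vary together, where these tests differ.

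Alternatives were DESeq2 1.42.0 and limma-voom, DESeq2 size factors and upper-quartile scaling, no filter or a stricter one (1 CPM in 4 libraries), the effective-length offset, only the groups compared, PLDLS against the mean of PLASS and EV, and leaving out each library. Where this left a group with 1 library, that library was assumed to vary like the other groups. Combining the block with these, and thinning every library to 5578688 reads, was chosen after seeing the data. A gene called in PLASS vs EV with the block is not reported here.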

Results

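Poly-A RNA was sequenced from MUTZ3, an acute myeloid leukaemia line with an inversion of chromosome 3, collected 72 h after retroviral transduction. One construct carried 4 copies of PLDLS, a motif by which proteins bind the CTBP corepressors. Per the labels this peptide inhibits the contact of CTBP with EVI1, a product of MECOM. The second carried the inactive PLASS peptide in the same backbone, and the third group received an empty vector (EV). Each of the 3 groups had 2 libraries, written below as PLASS 1 for PLASS replicate 1 and so on. The deposited tables held 16437109 and 5582078 estimated reads for PLDLS replicates 1 and 2, 20132920 and 12777337 for PLASS and 35800826 and 18932337 for EV, so precision was lowest in PLDLS 2. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

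The first principal component of log2 CPM (read counts scaled to library size) held 47.4% of the variance and separated the replicate numbers in all 3 groups. Libraries with the same number deviated together, although no label says that the number marks a shared day or batch, so values from a fit with the replicate number as a block are also given where a call differed. Unless another tool is named, calls and adjusted p are those of edgeR with its expression filter on all 6 libraries. Values in parentheses beside left-out libraries and other settings are adjusted p unless named log2. Beside member counts of lists, other tools means all calls with the block by DESeq2, limma-voom and edgeR with no filter, in this order.

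**Figure D1:**
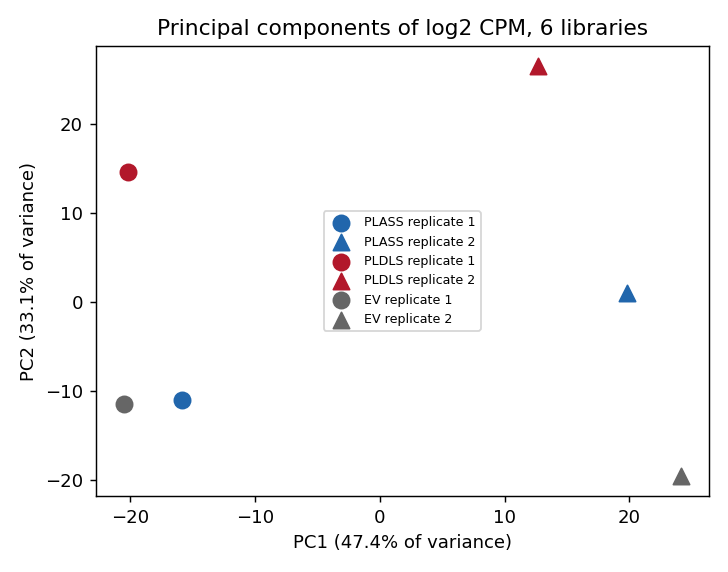
First and second principal components of log2 CPM for the 6 libraries, with colour for the group and marker shape for the replicate number. The first component (47.4% of variance) parts replicate 1 from replicate 2 in every group, and the second holds 33.1%.

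MECOM (GRCh38 chromosome 3, 169083507 to 169663712) encodes EVI1, a transcription factor that binds CTBP. It was at 562 ± 60.3 CPM with PLDLS, 436 ± 134 with PLASS and 108 ± 28.6 with EV (mean ± SD, n = 2). Construct reads may be among these and could not be told apart. CTBP1, a corepressor gene, was at 127 ± 17.3, 133 ± 17.8 and 134 ± 4.76 CPM in the same order, and its paralogue CTBP2 at 151 ± 34.9, 147 ± 21.8 and 155 ± 6.59 CPM. GATA2, a haematopoietic transcription factor gene, was at 161 ± 36.6, 205 ± 96.7 and 172 ± 57.5 CPM. In PLDLS vs PLASS no setting called any of these 4 genes, with log2 differences (± SE) with the block of 0.40 ± 0.14, -0.063 ± 0.13, 0.039 ± 0.14 and -0.29 ± 0.15. Their edgeR adjusted p were 0.295, 0.950, 0.972 and 0.553. Without the block the sign turned without 1 library for CTBP1, CTBP2 and GATA2.

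PLDLS vs PLASS set a peptide that, per the labels, inhibits the contact of EVI1 and CTBP against a similar peptide without that effect. The contact itself was not measured here. PMP22, a membrane protein gene of myelin, was at 33.6 ± 3.41 CPM with PLDLS and 4.52 ± 0.201 with PLASS (n = 2 each). ITGB7, an integrin subunit gene, was at 38.5 ± 9.91 and 6.06 ± 0.269 CPM, and CD207, which encodes the Langerhans cell lectin langerin, at 20.1 ± 0.104 and 3.29 ± 0.986 CPM. In the other direction, HLA-DOA, which encodes a modulator of MHC class II peptide loading, was at 6.49 ± 0.793 and 27.7 ± 2.05 CPM, and PREX2, a Rac exchange factor gene, at 2.32 ± 0.913 and 11.9 ± 0.40 CPM. With the block these 5 genes passed the threshold, at log2 2.89 ± 0.19 (SE), 2.64 ± 0.23, 2.58 ± 0.26, -2.13 ± 0.19 and -2.5 ± 0.27. Their edgeR adjusted p were 0.00205, 0.00411, 0.00575, 0.00418 and 0.00604 (1.13e-20 to 0.0373 over settings with the block). Without the block edgeR called none of the 5, with adjusted p of 0.0684, 0.0684, 0.115, 0.0684 and 0.118, while DESeq2 and edgeR with no filter called all 5 (adjusted p up to 6.56e-07 and 3.83e-06).

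Without the block, edgeR called 0 of 14631 genes in PLDLS vs PLASS, with 721 at an unadjusted p under 0.05, where chance gives 732. DESeq2 called 121 genes, limma-voom 0 and edgeR with no expression filter 240. With the block, edgeR called 297 genes, 222 higher and 75 lower with PLDLS, and all of them had the same sign within both replicate numbers. This count fell without a PLDLS or PLASS library and rose without either EV library, and the EV vectors differ. In 20 simulations of unchanged groups with the block, 2.3 genes on average and at most 8 were called. These held the number effect and the spread of the blocked fit. Such simulations do not show how many calls differences between cultures alone would give.

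Among genes past the threshold with the block, ADAMTS8, a secreted metalloprotease gene, had the largest difference upward (log2 3.12 ± 0.35). It was followed by PMP22, the transcription factor gene SP6 (2.76 ± 0.36), ITGB7, CD207, SH3PXD2B (2.46 ± 0.37), SLAMF1 (2.44 ± 0.35), KIAA0040 (2.44 ± 0.27) and GALNT3 (2.37 ± 0.31), then PRF1, which encodes perforin (2.30 ± 0.32), the natural killer receptor gene NCR2 (2.30 ± 0.27) and HSPA7 (2.22 ± 0.20). The largest differences downward were those of MARCKS (-2.83 ± 0.39), BCL2L2-PABPN1 (-2.78 ± 0.55), SIGLEC1 (-2.60 ± 0.45) and IRF8 (-2.5 ± 0.42), then PREX2, the BMP antagonist gene NOG (-2.45 ± 0.45), the interferon-induced MX1 (-2.22 ± 0.26), HLA-DOA and FLNC (-2.12 ± 0.27), TSPAN33 (-2.05 ± 0.34), IFIT5 (-1.95 ± 0.40) and CSRP2 (-1.93 ± 0.39). Adjusted p of these 24 genes lay between 0.00205 and 0.0473. HSPA7 shares sequence with other heat shock genes and BCL2L2-PABPN1 is a readthrough of neighbouring genes, so their counts are uncertain. BCL2L2-PABPN1 was at 1.32 and 0 CPM in PLDLS replicates 1 and 2, so the size of its difference depends on 1 library with no reads. Leaving out 1 library with the block ended calls without PLASS 1 for GALNT3 (0.0792), PRF1 (0.0664), IRF8 (0.0763), NOG (0.0668), TSPAN33 (0.117), IFIT5 (0.407) and CSRP2 (0.194), without PLASS 2 for CSRP2 (0.0810), without PLDLS 1 for SH3PXD2B (0.0714), SLAMF1 (0.0720), GALNT3 (0.0948), MARCKS (0.0710), SIGLEC1 (0.233), IRF8 (0.0650), NOG (0.408), FLNC (0.0635), TSPAN33 (0.126), IFIT5 (0.239) and CSRP2 (0.134) and without PLDLS 2 for IRF8 (0.0964), TSPAN33 (0.0824), IFIT5 (0.142) and CSRP2 (0.242). Calls also ended with the block by DESeq2 for BCL2L2-PABPN1 (0.181), IFIT5 (0.0695) and CSRP2 (0.101), by limma-voom for BCL2L2-PABPN1 (0.0739), IFIT5 (0.0672) and CSRP2 (0.0666), with the length offset for BCL2L2-PABPN1 (0.0506), IFIT5 (0.0506) and CSRP2 (0.0502) and after thinning for IRF8 (0.0935), IFIT5 (0.131) and CSRP2 (0.147). The fold with the block moved by over 1.5 times without 1 library (log2 given) for SP6 (3.48 without PLDLS 1 and 2.0 without PLDLS 2), SH3PXD2B (3.30 without PLASS 1), SLAMF1 (1.83 without PLDLS 1), MARCKS (-2.19 without PLASS 1), BCL2L2-PABPN1 (-3.60 without PLASS 1 and -9.81 without PLDLS 1), SIGLEC1 (-1.75 without PLDLS 1 and -3.31 without PLDLS 2) and NOG (-1.5 without PLDLS 1).

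Without the block the genes with the smallest p in PLDLS vs PLASS, none called by edgeR with its filter, were PMP22, ITGB7, MTURN (1.77 ± 0.19), GCOM1 (1.88 ± 0.21) and CD207 upward. Downward they were HLA-DOA, PREX2, RNF157 (-1.43 ± 0.24), COL6A2 (-1.53 ± 0.26) and MARCKS. DESeq2 and edgeR with no filter called all 10 without the block (adjusted p up to 0.000404 and 0.00218). With the block MTURN (1.77 ± 0.15), GCOM1 (1.88 ± 0.16), RNF157 (-1.42 ± 0.17) and COL6A2 (-1.51 ± 0.17) passed, with edgeR adjusted p of 0.00411, 0.00411, 0.00853 and 0.00698 (2.11e-19 to 0.0490 over settings with the block). GCOM1 is a readthrough gene, so its count is uncertain.

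**Figure D2:**
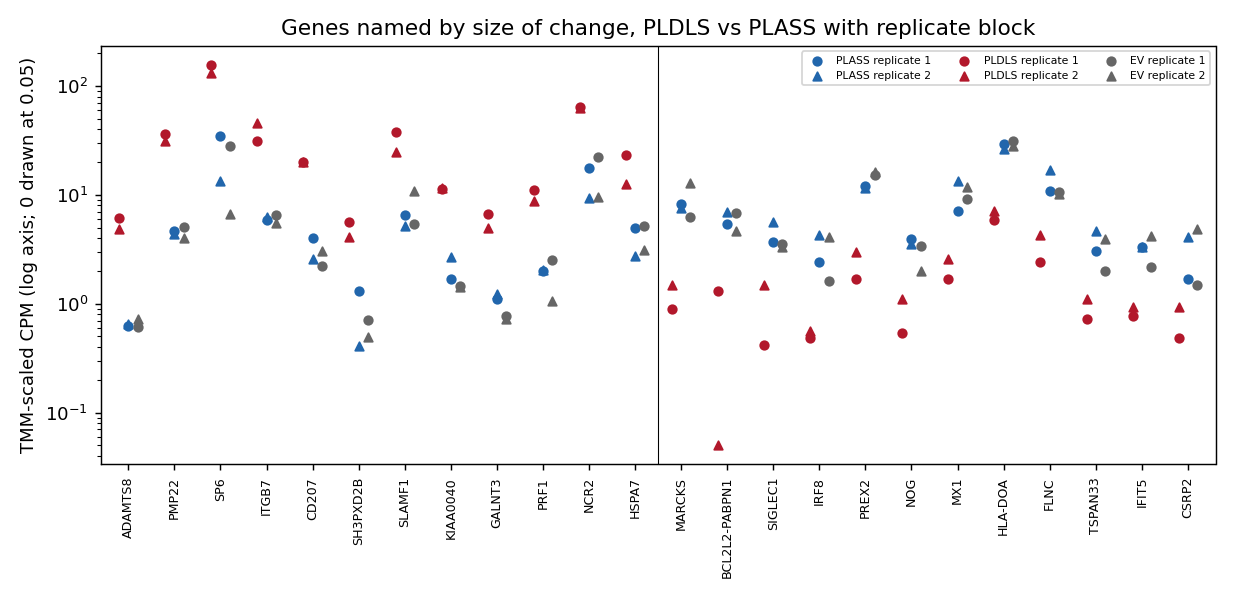
TMM-scaled CPM (log axis) of the 24 genes with the largest differences between PLDLS and PLASS among those past the threshold with the replicate block, where each point is 1 library. As the rule for naming genes required, both PLDLS libraries lie above both PLASS libraries for the 12 genes on the left and below them for the 12 on the right. Of all 14631 tested genes, 29.1% had no overlap between these groups. A value of 0 is drawn at 0.05.

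**Figure D3:**
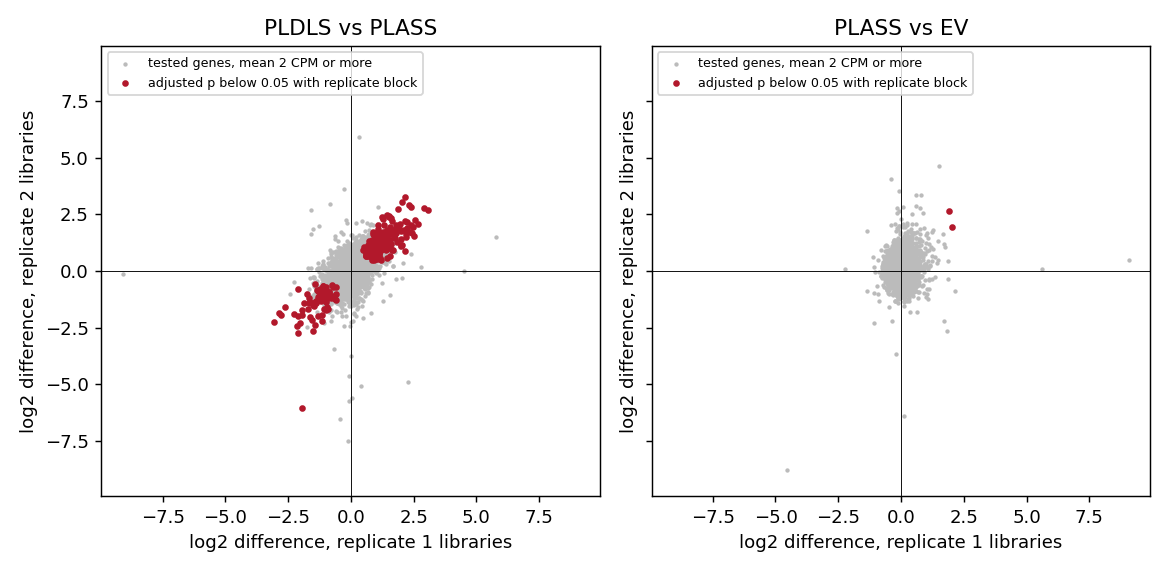
Log2 differences per gene in replicate 1 libraries (horizontal) and replicate 2 libraries (vertical) for PLDLS vs PLASS (left) and PLASS vs EV (right), with gray points for tested genes with a mean of at least 2 CPM and red points for genes with an edgeR adjusted p under 0.05 with the replicate block. Across genes, which are not independent replicates, the 2 axes correlate at r = 0.502 for PLDLS vs PLASS and 0.00229 for PLASS vs EV.

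Late granule and maturation genes of neutrophils were higher with PLDLS than with PLASS as a group (camera, adjusted p = 4.51e-06, 2.67e-07 to 0.689 over the alternatives). That call was lost with an adjusted p = 0.657 with an estimated correlation. With the block 3 of 9 tested members were higher and 0 lower (other tools 2, 4 and 5), and 6 were higher adjusted over the list alone. PADI4, a protein-arginine deiminase gene, was higher by log2 1.38 ± 0.21, CEBPE, a granulocyte transcription factor gene, by 1.30 ± 0.25 and MGAM by 0.74 ± 0.15, with edgeR adjusted p of 0.0179, 0.0396 and 0.0484 (2.44e-06 to 0.633 over settings with the block). CHI3L1 was at 2.93 ± 0.65 and was not called by edgeR with the block. With the block CHI3L1 passed without EV 1 (0.00669) or EV 2 (0.0111). With the block, other settings called CHI3L1 by limma-voom or with no filter or with 2 groups only. Among these genes, edgeR calls with the block were lost without PLASS 1 for PADI4 (0.0677), CEBPE (0.315) and MGAM (0.633), without PLASS 2 for CEBPE (0.127) and MGAM (0.213), without PLDLS 1 for CEBPE (0.167) and MGAM (0.299) and without PLDLS 2 for PADI4 (0.0948), CEBPE (0.155) and MGAM (0.206). With the block, calls ended by DESeq2 for CEBPE (0.110), after thinning for CEBPE (0.0805) and MGAM (0.0727), with upper-quartile scaling for MGAM (0.0599) and with DESeq2 size factors for MGAM (0.05).

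Myeloid transcription factor genes passed as a group, upward, with the block only (camera, adjusted p = 0.0403 with the block and 0.124 without it, 0.00357 to 0.689 over the alternatives). The list had an adjusted p = 0.651 with an estimated correlation and the block. Of 25 tested members 4 were higher and 2 lower with the block (other tools 9, 8 and 10), or 7 and 4 adjusted over the list alone. GFI1B was higher by log2 1.76 ± 0.24 and CEBPA, a granulocyte lineage factor gene, by 1.45 ± 0.21. IRF8, a monocyte and dendritic cell factor gene, differed by -2.5 ± 0.42 and GFI1 by -1.15 ± 0.21. Their edgeR adjusted p were 0.0110, 0.0126, 0.0223 and 0.0319 (2.70e-10 to 0.161 over settings with the block). Calls with the block were lost without PLASS 1 for IRF8 (0.0763), without PLASS 2 for GFI1 (0.161), without PLDLS 1 for IRF8 (0.0650) and GFI1 (0.154) and without PLDLS 2 for IRF8 (0.0964) and GFI1 (0.0821). Other choices with the block ended calls after thinning for IRF8 (0.0935). The call of myeloid factor genes was lost without PLASS 1 (0.326) or PLDLS 2 (0.135) in the blocked fit.

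Genes of G2/M and mitosis were lower with PLDLS as a group (camera, 25 genes, adjusted p = 2.83e-12, 1.10e-23 to 0.689 over the alternatives; adjusted p = 0.657 with an estimated correlation). With the block edgeR called 1 member (other tools 5, 2 and 5), the cyclin B1 gene CCNB1 (log2 -0.69 ± 0.13, edgeR adjusted p = 0.0331, 0.000510 to 0.506 over settings with the block), and 15 members were lower adjusted over the list alone. With the block CCNB1 lost its call without PLASS 1 (0.506), PLASS 2 (0.162), PLDLS 1 (0.244) or PLDLS 2 (0.136). The spindle checkpoint gene BUB1 was at -0.62 ± 0.13, HMMR at -0.72 ± 0.17 and the topoisomerase gene TOP2A at -0.57 ± 0.13, not called by edgeR with the block. BUB1 (0.00257), HMMR (0.00214) and TOP2A (0.00547) passed with the block without EV 1, as did BUB1 (0.00587), HMMR (0.00425) and TOP2A (0.0102) without EV 2. Other blocked settings called BUB1 with upper-quartile scaling or by limma-voom and BUB1, HMMR and TOP2A by DESeq2 or with no filter or with 2 groups only. Of this list, 9 of 25 genes were also lower in replicate 2 than in replicate 1.

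DNA replication genes were lower with PLDLS as a group (camera, 32 genes, adjusted p = 0.000150, 4.76e-15 to 0.799 over the alternatives; adjusted p = 0.745 with an estimated correlation). Among single genes edgeR called 0 genes with or without the block, with 10 and 2 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0, and 0 were lower adjusted over the list alone. The licensing gene CDC6 was at log2 -0.46 ± 0.13, GINS1 at -0.52 ± 0.15, the polymerase gene POLE at -0.47 ± 0.15 and the helicase subunit gene MCM2 at -0.36 ± 0.13. CDC6 (0.0166), GINS1 (0.0245), POLE (0.0124) and MCM2 (0.0453) passed with the block without EV 1, as did CDC6 (0.0238), GINS1 (0.0319) and POLE (0.0198) without EV 2. Other settings with the block called CDC6, GINS1, POLE and MCM2 with 2 groups only. The call of replication genes was lost without PLASS 2 (0.760) and turned direction without PLDLS 1 (0.608) in the unblocked fit. The sign of MCM2 (0.0046 without PLASS 2 and 0.00059 without PLDLS 1) turned without the block. Of this list, 24 of 32 genes were higher in replicate 2 than in replicate 1.

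NF-kB and inflammatory genes were lower with PLDLS as a group (camera, 22 genes, adjusted p = 4.72e-06, 1.26e-20 to 0.796 over the alternatives; adjusted p = 0.657 with an estimated correlation). With the block 5 members were lower and 0 higher (other tools 9, 5 and 12), and 12 were lower adjusted over the list alone. The adhesion molecule gene ICAM1 was at log2 -0.88 ± 0.15, the NF-kB subunit genes RELB at -0.95 ± 0.18 and NFKB2 at -0.90 ± 0.18, and the cytokine gene TNF at -1.30 ± 0.26. Their edgeR adjusted p were 0.0246, 0.0347, 0.0466 and 0.0447 (3.73e-05 to 0.496 over settings with the block). With the block and 1 library left out, calls were lost without PLASS 1 for ICAM1 (0.244), RELB (0.496), NFKB2 (0.440) and TNF (0.111), without PLASS 2 for TNF (0.0907), without PLDLS 1 for ICAM1 (0.0635), RELB (0.194) and NFKB2 (0.0833) and without PLDLS 2 for ICAM1 (0.170), RELB (0.112), NFKB2 (0.241) and TNF (0.245). Calls also ended with the block with the length offset for NFKB2 (0.0611) and TNF (0.0535) and after thinning for TNF (0.0807). The call of NF-kB genes was lost without PLASS 2 (0.183) in the unblocked fit. The sign of ICAM1 (0.14 without PLASS 2) turned without the block. Of this list, 13 of 22 genes were higher in replicate 2 than in replicate 1.

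Interferon-stimulated genes were lower with PLDLS as a group (camera, 26 genes, adjusted p = 4.72e-06, 1.34e-06 to 0.656 over the alternatives; adjusted p = 0.656 with an estimated correlation), but members went both ways. With the block 2 were higher and 3 lower (other tools 4, 3 and 8), or 2 and 8 adjusted over the list alone. MX1 and XAF1 (-1.17 ± 0.24) were lower, and the antiviral genes RSAD2 (0.72 ± 0.14) and CMPK2 (0.70 ± 0.14) higher. Their edgeR adjusted p were 0.00838, 0.0471, 0.0410 and 0.0447 (4.37e-06 to 0.622 over settings with the block). Leaving out 1 library with the block ended calls without PLASS 1 for XAF1 (0.107), RSAD2 (0.622) and CMPK2 (0.291), without PLASS 2 for XAF1 (0.194), RSAD2 (0.181) and CMPK2 (0.478), without PLDLS 1 for XAF1 (0.321), RSAD2 (0.293) and CMPK2 (0.180) and without PLDLS 2 for XAF1 (0.142), RSAD2 (0.155) and CMPK2 (0.255). With the block, calls ended by DESeq2 for XAF1 (0.0646), by limma-voom for XAF1 (0.05003), with the length offset for XAF1 (0.0541), after thinning for XAF1 (0.0729) and CMPK2 (0.0732) and with upper-quartile scaling for CMPK2 (0.0514).

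MHC class II genes were lower with PLDLS as a group (camera, 12 genes, adjusted p = 1.26e-05, 1.83e-07 to 0.689 over the alternatives; adjusted p = 0.657 with an estimated correlation). HLA-DOA and HLA-DQA1 (-0.90 ± 0.18, edgeR adjusted p = 0.0421, 0.000692 to 0.623 over settings with the block) passed with the block (other tools 2, 2 and 2), and 3 members were lower adjusted over the list alone. HLA-DQB1 was at -0.51 ± 0.14 and CIITA, the class II transactivator gene, at -0.38 ± 0.22. HLA genes share sequence, so their counts are uncertain. With the block HLA-DQB1 passed without EV 1 (0.00972) or EV 2 (0.0145). With the block, other settings called HLA-DQB1 and CIITA with 2 groups only. With the block HLA-DQA1 lost its call without PLASS 1 (0.623), PLDLS 1 (0.299) or PLDLS 2 (0.112). The call of MHC class II genes was lost without PLDLS 1 (0.102) in the unblocked fit.

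Hypoxia and glycolysis genes passed upward with the block only (camera, 26 genes, adjusted p = 0.0109 with the block and 0.0543 without it, 7.57e-05 to 0.796 over the alternatives; adjusted p = 0.651 with an estimated correlation and the block). The glucose transporter gene SLC2A3 (1.21 ± 0.18) and NDRG1 (0.85 ± 0.15) were the 2 members called by edgeR (other tools 2, 2 and 3), and 2 were higher adjusted over the list alone. EGLN3 was at 1.20 ± 0.34 and ADM at 0.84 ± 0.27. With the block EGLN3 passed without EV 1 (0.0147) or EV 2 (0.0214). Other blocked settings called EGLN3 with no filter or with 2 groups only. Among these genes, edgeR calls with the block were lost without PLASS 1 for SLC2A3 (0.0825) and NDRG1 (0.475), without PLDLS 1 for NDRG1 (0.207) and without PLDLS 2 for SLC2A3 (0.0803). The call of hypoxia genes was lost without PLASS 1 (0.0883) in the blocked fit. Without the block the sign turned for ADM (-0.10 without PLASS 1 and -0.0092 without PLDLS 2). In replicate 2, 7 of 26 (2 lower) hypoxia genes were higher than in replicate 1, ADM (1.56 ± 0.21) and NDRG1 (0.60 ± 0.12) among them.

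Dendritic and Langerhans cell markers passed downward with the block only (camera, 18 genes, adjusted p = 0.0240 with the block and 0.0805 without it, 2.37e-05 to 0.813 over the alternatives; adjusted p = 0.721 with an estimated correlation and the block), although CD207 was higher. With the block 1 member was higher and 2 lower (other tools 3, 2 and 4), or 1 and 5 adjusted over the list alone. IRF8 and CD83 (-1.10 ± 0.22), a maturation marker gene of dendritic cells, were the lower ones, and CLEC9A was at -1.13 ± 0.31. With the block CLEC9A passed without PLASS 2 (0.0321), EV 1 (0.0207) or EV 2 (0.0276). Other settings with the block called CLEC9A with no filter or with 2 groups only. Calls with the block were lost without PLASS 1 for CD83 (0.285) and IRF8 (0.0763), without PLDLS 1 for CD83 (0.0538) and IRF8 (0.0650) and without PLDLS 2 for CD83 (0.253) and IRF8 (0.0964). Other choices with the block ended calls by limma-voom for CD83 (0.0585), with the length offset for CD83 (0.0506) and after thinning for IRF8 (0.0935). The call of dendritic markers was lost without PLASS 1 (0.813) or PLDLS 1 (0.144) in the blocked fit. Without the block the sign turned for CD83 (0.053 without PLASS 2) and CLEC9A (0.012 without PLASS 1).

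**Figure D4:**
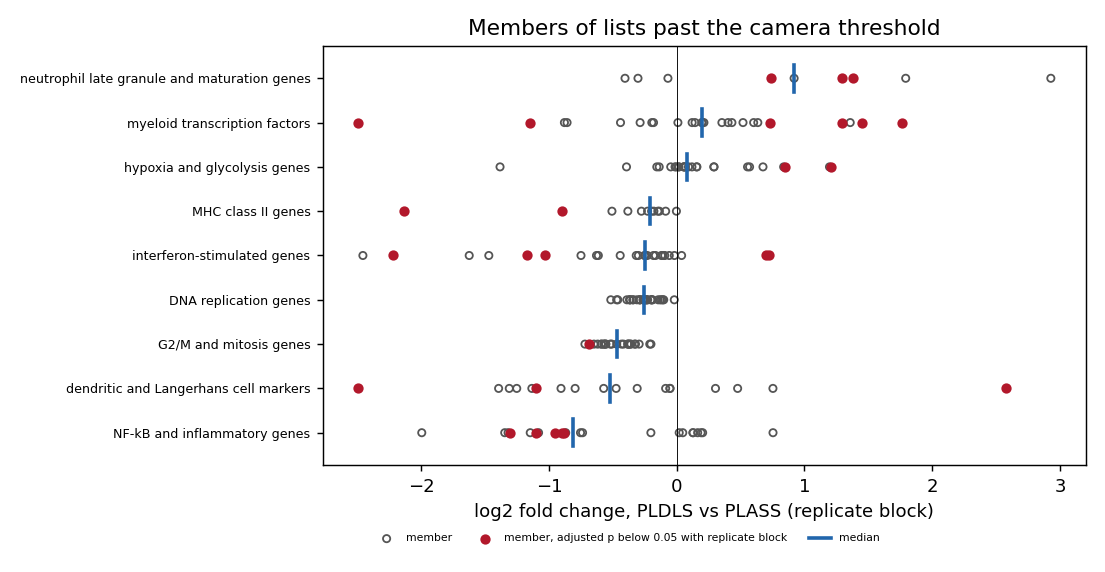
Log2 fold change between PLDLS and PLASS with the replicate block for each tested member of the 9 lists that passed camera with the preset correlation and the block, with filled red points for an edgeR adjusted p under 0.05 and blue bars for medians. No list passed with an estimated correlation.

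Other lists did not pass in PLDLS vs PLASS but held members that did with the block. S100A9 (1.51 ± 0.18) and S100A8 (1.96 ± 0.24), calcium-binding protein genes of the monocyte list, were higher, as were RNASE2 of the primary granule list (2.07 ± 0.30) and HDC, the histidine decarboxylase gene of the mast cell list (1.49 ± 0.21). In the stem and progenitor list HLF was lower (-1.13 ± 0.15) and HOXA9 higher (0.73 ± 0.14), and in the cholesterol and fatty acid list SREBF1 was lower (-0.94 ± 0.18) and SQLE higher (0.75 ± 0.14). Among 11 tested genes reported as EVI1 targets edgeR called CEBPA alone with the block, with ITGA6 at 0.47 ± 0.18. Among 22 genes of CTBP partners it called ZEB2 alone (1.01 ± 0.19), with NRIP1 at -0.52 ± 0.18. The edgeR adjusted p of S100A9, S100A8, RNASE2, HDC, HLF, HOXA9, SREBF1, SQLE and ZEB2 were 0.00853, 0.00853, 0.0135, 0.0124, 0.0104, 0.0388, 0.0408, 0.0328 and 0.0391 (3.23e-09 to 0.535 over settings with the block). ITGA6 (0.0208) and NRIP1 (0.0120) passed with the block without EV 1, as did ITGA6 (0.0423) and NRIP1 (0.0173) without EV 2. With the block, other settings called ITGA6 and NRIP1 with 2 groups only. With the block and 1 library left out, calls were lost without PLASS 1 for HLF (0.0991), HOXA9 (0.285), SQLE (0.535) and ZEB2 (0.428), without PLASS 2 for HOXA9 (0.319), SREBF1 (0.414) and SQLE (0.0736), without PLDLS 1 for RNASE2 (0.0503), HLF (0.0872), HOXA9 (0.0720), SREBF1 (0.0650), SQLE (0.235) and ZEB2 (0.235) and without PLDLS 2 for HDC (0.0693), HOXA9 (0.260), SREBF1 (0.242) and SQLE (0.0733). Between replicate numbers, S100A9 (0.76 ± 0.15), S100A8 (1.15 ± 0.19), RNASE2 (2.09 ± 0.24) and HDC (1.01 ± 0.17) were also higher in replicate 2 and HLF (-0.97 ± 0.12) and HOXA9 (-1.33 ± 0.12) lower (adjusted p up to 0.0135), and 7 of 12 mast cell, basophil and eosinophil markers and 15 of 24 cholesterol and fatty acid genes were higher.

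As checks for other cells, the lymphoid list had PRF1 higher and the interleukin receptor gene IL7R lower with PLDLS than with PLASS (-1.32 ± 0.21, edgeR adjusted p = 0.0201, 6.69e-07 to 0.0604 over settings with the block). Leaving out 1 library with the block ended calls without PLASS 1 for PRF1 (0.0664) and without PLDLS 2 for IL7R (0.0604). For 7 tested epithelial markers edgeR called 0 genes with or without the block, with 1 and 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0 and edgeR with no filter 1 and 0. For 4 stromal and endothelial markers edgeR called 0 genes with or without the block, with 0 and 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. KRT17 was at -1.24 ± 0.27. With the block KRT17 passed without EV 1 (0.0137) or EV 2 (0.0173). Other blocked settings called KRT17 with the length offset or with no filter or with 2 groups only.

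PLDLS vs EV set the active peptide construct against the empty vector. Per the labels, both peptide constructs carried 3 FLAG tags and 3 nuclear localisation signals. Only the tags are named for EV 1 and neither for EV 2, so differences may come partly from these. PMP22 (log2 2.88 ± 0.26, with 4.54 ± 0.799 CPM in EV, n = 2) and MTURN (2.08 ± 0.19, with 226 ± 15.1 CPM in PLDLS and 53.4 ± 7.91 in EV) were higher with PLDLS without the block. Both had an edgeR adjusted p of 0.0386 (1.23e-17 to 0.320 over settings without the block). They were the 2 genes that edgeR called without the block, with 1047 at an unadjusted p under 0.05. This count was 13 without PLASS 1, 14 without PLASS 2 and 0 without either PLDLS or either EV library. Next by p, and not called by edgeR without the block, were ITGB7 (2.67 ± 0.28), CD207 (2.94 ± 0.33) and GCOM1 (1.86 ± 0.21) upward and HLA-DOA (-2.21 ± 0.24), PREX2 (-2.85 ± 0.33), TNFRSF21 (-1.74 ± 0.24), MEIOC (-1.89 ± 0.29) and MARCKS (-3.10 ± 0.49) downward. Without the block their edgeR adjusted p were 0.0563, 0.0563, 0.0563, 0.0563, 0.0638, 0.0698, 0.0868 and 0.0966 in this order. In the unblocked fit calls appeared without PLASS 1 for ITGB7 (0.0195), CD207 (0.0195), GCOM1 (0.0453), HLA-DOA (0.0405) and PREX2 (0.0436) and without PLASS 2 for ITGB7 (0.0211), CD207 (0.0211), GCOM1 (0.0440), HLA-DOA (0.0376) and PREX2 (0.0394). Unblocked, other settings called ITGB7, CD207, GCOM1, HLA-DOA, PREX2, TNFRSF21, MEIOC and MARCKS by DESeq2 or with no filter, ITGB7, CD207 and GCOM1 by limma-voom or after thinning, ITGB7 and HLA-DOA with the length offset and ITGB7 and CD207 with 2 groups only. With the block all 8 passed. Their edgeR adjusted p then were 0.00161, 0.00161, 0.00161, 0.00161, 0.00182, 0.00271, 0.00453 and 0.00451 in the same order (9.72e-19 to 0.0340 over settings with the block). Without EV 1 the fold of MARCKS with the block moved by over 1.5 times (log2 -3.59).

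With the block 621 genes passed in PLDLS vs EV, 474 higher and 147 lower. Across genes, which are not independent replicates, the log2 differences of PLDLS vs EV within replicate numbers 1 and 2 correlated at r = 0.466. The count of 621 was 283 (232 higher) without PLDLS 1, 332 (259 higher) without PLDLS 2 and 2143 (1220 higher) without EV 1. The largest differences upward were those of SP6 (3.32 ± 0.36), the haem oxygenase gene HMOX1 (3.28 ± 0.53), ADAMTS8 (3.09 ± 0.32), the transcription factor gene RUNX2 (3.08 ± 0.35), SH3PXD2B (3.0 ± 0.37) and GALNT3 (3.0 ± 0.31). Downward they were those of MARCKS (-2.99 ± 0.38), PREX2 (-2.89 ± 0.26), BCL2L2-PABPN1 (-2.67 ± 0.53), MX1 (-2.33 ± 0.26), GTF2IP1 (-2.26 ± 0.30), a pseudogene that shares sequence with its parent gene, and HLA-DOA (-2.23 ± 0.19). HMOX1 was at 9.52 and 29.5 CPM in PLDLS replicates 1 and 2 and 1.90 and 0.995 in EV, and BCL2L2-PABPN1 at 0 in PLDLS 2. All 12 kept their calls without each of the 6 libraries in turn. Calls ended with the block by DESeq2 for BCL2L2-PABPN1 (0.183). The fold with the block moved by over 1.5 times without 1 library (log2 given) for SP6 (4.09 without PLDLS 1, 2.60 without PLDLS 2, 4.07 without EV 1 and 2.70 without EV 2), HMOX1 (4.94 without EV 1 and 2.24 without EV 2), RUNX2 (2.45 without PLDLS 1), MARCKS (-3.59 without EV 1) and BCL2L2-PABPN1 (-9.73 without PLDLS 1). MECOM was higher by 2.40 ± 0.15 with the block (edgeR adjusted p = 0.000803, 1.13e-42 to 0.00138 over settings with the block), and had an adjusted p = 0.0638 without it. In the unblocked fit calls appeared without PLASS 2 for MECOM (0.0152), RUNX2 (0.0497) and GTF2IP1 (0.0440) and without PLASS 1 for MECOM (0.0146) and RUNX2 (0.0466). Unblocked, other settings called MECOM by DESeq2 or with no filter or with 2 groups only. Its rise may hold construct reads.

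Against EV the G2/M, replication, interferon and MHC class II lists passed camera downward with PLDLS and the late neutrophil granule list upward, none with an estimated correlation. For G2/M and mitosis genes camera gave an adjusted p = 3.44e-07, 1.23e-14 to 0.692 over the alternatives (adjusted p = 0.692 with an estimated correlation), and of 25 genes CCNB1 (-0.61 ± 0.12) and BUB1 (-0.62 ± 0.13) passed with the block, or 9 genes adjusted over the list alone. For DNA replication genes it gave an adjusted p = 7.61e-05, 7.92e-15 to 0.949 over the alternatives (adjusted p = 0.729 with an estimated correlation). Among replication genes edgeR called 0 genes with or without the block, with 15 and 2 at an unadjusted p under 0.05, and DESeq2 called 1 and 0, limma-voom 0 and 0 and edgeR with no filter 2 and 0. With the block 12 were lower adjusted over the list alone, and CDC6 was at -0.52 ± 0.13 and GINS1 at -0.57 ± 0.15. For interferon-stimulated genes it gave an adjusted p = 2.07e-05, 3.51e-06 to 0.614 over the alternatives (adjusted p = 0.596 with an estimated correlation), with 6 lower, IFI6 (-1.38 ± 0.21) among them, and 2 higher with the block, or 11 and 2 adjusted over the list alone. For MHC class II genes it gave an adjusted p = 4.53e-05, 3.88e-07 to 0.692 over the alternatives (adjusted p = 0.692 with an estimated correlation), with HLA-DOA and HLA-DQA1 (-0.89 ± 0.18) of 12 lower with the block, also adjusted over the list alone. For the granule genes it gave an adjusted p = 6.09e-05, 1.80e-06 to 0.692 over the alternatives (adjusted p = 0.692 with an estimated correlation), with 3 members higher with the block, PADI4 (1.31 ± 0.21) and CEBPE (1.5 ± 0.24) among them, or 6 adjusted over the list alone. With the block DESeq2, limma-voom and edgeR with no filter called 6, 2 and 6 G2/M, 9, 8 and 9 interferon-stimulated, 2, 2 and 2 MHC class II and 3, 5 and 5 granule genes.

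In PLDLS vs EV the call of G2/M genes was lost without EV 1 (0.0508) in the unblocked fit. The call of replication genes was lost without PLDLS 1 (0.949) or EV 2 (0.607) in the unblocked fit. The call of MHC class II genes was lost without PLDLS 1 (0.0571) in the unblocked fit. CDC6 (0.0192) and GINS1 (0.0352) passed with the block without EV 1. Other settings with the block called CDC6 by DESeq2 or with the length offset or with no filter. Among these genes, edgeR calls with the block were lost without PLASS 1 for CCNB1 (0.0666) and BUB1 (0.0595), without PLASS 2 for CCNB1 (0.0523), without PLDLS 1 for CCNB1 (0.224), BUB1 (0.295), HLA-DQA1 (0.202) and CEBPE (0.0682) and without PLDLS 2 for CCNB1 (0.123), BUB1 (0.0747), HLA-DQA1 (0.0739), IFI6 (0.0562) and PADI4 (0.0668). In replicate 2, 24 of 32 replication genes were higher and 9 of 25 G2/M lower.

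MYC and ribosome biogenesis genes were lower with PLDLS than with EV as a group (camera, adjusted p = 0.00344, 3.33e-08 to 0.933 over the alternatives; adjusted p = 0.729 with an estimated correlation). Of 28 tested members edgeR called 0 genes with or without the block, with 5 and 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0 and edgeR with no filter 1 and 0, and 0 were lower adjusted over the list alone. LYAR was at -0.69 ± 0.20, not called by edgeR. With the block LYAR passed without EV 1 (0.00391). With the block, other settings called LYAR with no filter. The call of MYC and ribosome genes was lost without PLDLS 1 (0.0600) and turned direction without EV 2 (0.933) in the unblocked fit, and was lost without PLDLS 2 (0.379) or EV 2 (0.276) in the blocked fit. Immediate early genes were higher (camera, adjusted p = 0.0222, 1.75e-06 to 0.895 over the alternatives; adjusted p = 0.821 with an estimated correlation), with EGR3 (1.05 ± 0.18) and KLF6 (0.84 ± 0.20) past the threshold with the block (other tools 4, 2 and 5) and 7 adjusted over the list alone. The call of immediate early genes was lost without EV 1 (0.895) and turned direction without PLDLS 2 (0.796) in the unblocked fit, and was lost without EV 2 (0.210) in the blocked fit. Without the block the sign turned for EGR3 (-0.073 without PLDLS 2). In replicate 2, 16 of 21 immediate early and 7 of 28 (1 lower) MYC and ribosome genes were higher.

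Hypoxia and glycolysis genes were higher with PLDLS than with EV (camera, adjusted p = 0.0463, 0.00225 to 0.729 over the alternatives; adjusted p = 0.729 with an estimated correlation), with NDRG1 (1.34 ± 0.15) and SLC2A3 (1.38 ± 0.18) past the threshold with the block (other tools 4, 4 and 4). Adjusted over the list alone, 5 were higher and 1 lower. The call of hypoxia genes was lost without PLDLS 2 (0.553) or EV 1 (0.513) in the unblocked fit. It was also lost with DESeq2 size factors (adjusted p = 0.0503). Lysosome genes were higher (camera, adjusted p = 0.0498, 0.00134 to 0.809 over the alternatives; adjusted p = 0.729 with an estimated correlation), with CD63 (0.57 ± 0.13) past the threshold with the block (other tools 1, 1 and 1), 1 adjusted over the list alone and the cholesterol transporter gene NPC2 at 0.41 ± 0.17. The call of lysosome genes was lost without PLASS 1 (0.0611), PLASS 2 (0.0718), PLDLS 2 (0.798), EV 1 (0.119) or EV 2 (0.124) in the unblocked fit, and was lost without PLASS 1 (0.0612), PLASS 2 (0.0687), PLDLS 2 (0.532) or EV 2 (0.809) in the blocked fit. With DESeq2 size factors it was lost too (adjusted p = 0.0597). Calls with the block were lost without PLASS 1 for CD63 (0.113), without PLASS 2 for CD63 (0.134), without PLDLS 1 for CD63 (0.225), EGR3 (0.115) and KLF6 (0.368), without PLDLS 2 for CD63 (0.292) and EGR3 (0.0508) and without EV 2 for KLF6 (0.0555). With the block, calls ended after thinning for EGR3 (0.0912), with upper-quartile scaling for KLF6 (0.0547), with DESeq2 size factors for CD63 (0.0511) and KLF6 (0.0550), with 2 groups only for CD63 (0.111) and with the stricter filter for KLF6 (0.0513). In replicate 2, 7 of 26 (2 lower) hypoxia genes were higher.

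With the block only, stem and progenitor genes were lower with PLDLS than with EV (camera, adjusted p = 0.0133 with the block and 0.0751 without it, 0.00165 to 0.692 over the alternatives; adjusted p = 0.614 with an estimated correlation and the block). Of 21 members 6 were lower (other tools 8, 6 and 8), or 6 lower and 3 higher adjusted over the list alone, and HLF was at -1.70 ± 0.15 and MLLT3 at -1.17 ± 0.15. Stress response genes of the unfolded protein and integrated pathways were higher (camera, adjusted p = 0.0247 with the block and 0.0916 without it, 6.83e-06 to 0.692 over the alternatives; adjusted p = 0.614 with an estimated correlation and the block), with 3 of 23 past the threshold (other tools 4, 3 and 5) and 5 adjusted over the list alone. DDIT4, an inhibitor gene of mTORC1, was at 1.81 ± 0.31 and the cystine transporter gene SLC7A11 at 1.34 ± 0.24. With the block SLC7A11 lost its call without PLDLS 1 (0.132). The fold with the block moved by over 1.5 times without 1 library (log2 given) for DDIT4 (2.57 without EV 1 and 1.15 without EV 2). The call of stem and progenitor genes was lost without PLDLS 1 (0.117) or EV 1 (0.0909) in the blocked fit. The call of stress response genes was lost without PLDLS 1 (0.0817) or EV 2 (0.210) in the blocked fit. In replicate 2, 10 of 21 (1 higher) stem and progenitor genes were lower.

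Cholesterol and fatty acid synthesis genes were higher with PLDLS than with EV with the block only (camera, adjusted p = 0.0120 with the block and 0.0916 without it, 4.74e-05 to 0.917 over the alternatives; adjusted p = 0.614 with an estimated correlation and the block). With the block 2 members were higher and 1 lower (other tools 5, 3 and 6), or 6 and 2 adjusted over the list alone. The squalene epoxidase gene SQLE was at 1.29 ± 0.14 and INSIG1 at 1.09 ± 0.15. NF-kB and inflammatory genes were lower with the block only (camera, adjusted p = 0.0424 with the block and 0.0916 without it, 1.69e-11 to 0.882 over the alternatives; adjusted p = 0.802 with an estimated correlation and the block), with 4 members lower (other tools 5, 5 and 10), or 8 lower and 4 higher adjusted over the list alone. RELB was at -1.02 ± 0.18 and NFKB2 at -0.96 ± 0.18. With the block and 1 library left out, calls were lost without PLDLS 1 for RELB (0.0973) and without PLDLS 2 for RELB (0.0558) and NFKB2 (0.137). The call of cholesterol and fatty acid genes was lost without PLDLS 2 (0.0527) or EV 2 (0.270) in the blocked fit, and in the unblocked fit they turned direction without PLDLS 2 (0.576) or EV 1 (0.917). The call of NF-kB genes turned direction without PLDLS 2 (0.532) or EV 2 (0.210) in the blocked fit, and in the unblocked fit they passed in the other direction without EV 2 (5.13e-05). In replicate 2, 15 of 24 cholesterol and fatty acid and 13 of 22 NF-kB genes were higher.

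Of the genes called with the block, 213 were higher and 67 lower with PLDLS than with both PLASS and EV, and 0 had opposite signs. Both comparisons use the PLDLS libraries. Independent lists of these sizes would share 7.19 higher and 0.754 lower genes, and simulated unchanged groups shared 0.750 on average and at most 3. Across 12076 genes the fold changes correlated at r = 0.847, against 0.547 in the simulation, with a covariance of 0.131 against 0.0297. The shared count of 280 was 78 without PLASS 1, 132 without PLDLS 1, 132 without PLDLS 2, 784 without EV 1 and 521 without EV 2. In a comparison chosen after seeing the data, no library was shared, since each difference was taken within 1 replicate number. Across the same genes, which are not independent replicates, log2 differences of PLDLS vs PLASS in number 1 and PLDLS vs EV in number 2 correlated at r = 0.521 (covariance 0.123), and those of PLDLS vs PLASS in number 2 and PLDLS vs EV in number 1 at r = 0.440 (covariance 0.0858). No genes could be called this way, so part of the excess of shared calls may come from the shared libraries. Without the block edgeR called 0 genes in PLDLS vs PLASS (721 at an unadjusted p under 0.05), so none could be shared, while fold changes correlated at r = 0.839. DESeq2 shared 109, limma-voom 0 and edgeR with no filter 215.

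PLASS vs EV set the inactive construct, its tags and localisation signals included, against the empty vector. MECOM was higher with PLASS by log2 2.0 ± 0.15 with the block (edgeR adjusted p = 0.00563, 3.38e-29 to 0.00746 over settings with the block), and by 2.01 ± 0.28 without it (adjusted p = 1). Unblocked, DESeq2 and edgeR with no filter called MECOM. At least 94.1% of MECOM reads in each peptide library lay on 3 of its transcripts, against 56.6% and 66.9% in EV replicates 1 and 2. This rise may hold construct reads. With the block edgeR called 2 genes, against 5 false calls in simulated data where PLASS and EV did not differ. Without the block edgeR called 0 genes (101 at an unadjusted p under 0.05), DESeq2 3, limma-voom 0 and edgeR with no filter 33.

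**Figure D5:**
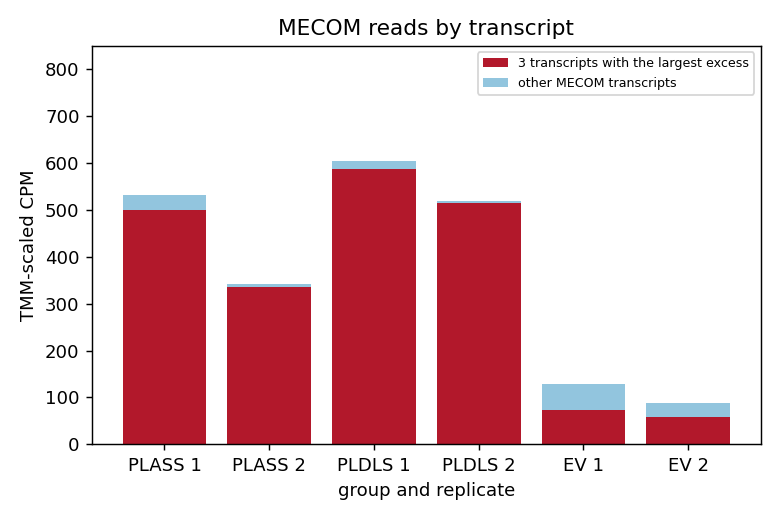
TMM-scaled CPM of MECOM in each library, stacked into the 3 transcripts with the largest excess and all other MECOM transcripts. The 4 peptide libraries hold between 342 and 605 CPM, and the EV libraries 129 and 88.2 CPM.

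Apart from MECOM, the genes with the smallest p in PLASS vs EV without the block, none called by edgeR with its filter, were GJA3 (1.49 ± 0.31), CRIP2 (1.45 ± 0.33), HRH1 (1.12 ± 0.27) and ELFN1 (1.56 ± 0.39) upward. Downward they were SENP3-EIF4A1 (-1.53 ± 0.44), ITPRIPL1 (-0.67 ± 0.21), SMN2 (-5.25 ± 1.72), C2CD2 (-0.67 ± 0.22) and LRFN1 (-0.84 ± 0.32). With the block ID2 (1.42 ± 0.18), KLF10 (1.10 ± 0.17), ARRDC4 (0.70 ± 0.12) and PIM1 (-0.47 ± 0.13) came among the smallest p and were not called by edgeR. SENP3-EIF4A1 is a readthrough gene and SMN2 has the near-identical copy SMN1, so their counts are uncertain. GJA3 (0.0133), CRIP2 (0.00136), HRH1 (0.0220), SENP3-EIF4A1 (0.00211), ITPRIPL1 (0.0120), SMN2 (2.61e-09), C2CD2 (0.00917), ID2 (0.00146), KLF10 (0.00114) and ARRDC4 (0.0155) passed with the block without EV 1, as did GJA3 (0.0160), CRIP2 (0.0357), SENP3-EIF4A1 (0.0104), SMN2 (0.0279) and KLF10 (0.0163) without PLASS 1, SMN2 (0.00994) and ID2 (0.00850) without PLASS 2, SMN2 (0.00595) and ID2 (0.0296) without PLDLS 1, SMN2 (0.00218) and ID2 (0.0215) without PLDLS 2 and SMN2 (1.93e-05) and ID2 (0.000678) without EV 2. Other blocked settings called GJA3, CRIP2, SENP3-EIF4A1, ID2, KLF10 and ARRDC4 by DESeq2, GJA3, CRIP2, HRH1, ELFN1, SENP3-EIF4A1, SMN2, ID2, KLF10 and ARRDC4 with no filter and SMN2 and ID2 with 2 groups only. Unblocked, other settings called GJA3, CRIP2, SENP3-EIF4A1, SMN2, ID2 and KLF10 with no filter.

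As groups, immediate early genes were higher with PLASS than with EV (camera, adjusted p = 4.69e-10, 2.12e-38 to 0.996 over the alternatives; adjusted p = 0.956 with an estimated correlation), with EGR3 at log2 0.81 ± 0.18 with the block. Stress response genes of the unfolded protein and integrated pathways were higher (camera, adjusted p = 5.96e-08, 1.20e-13 to 0.996 over the alternatives; adjusted p = 0.266 with an estimated correlation), with SLC7A11 at 1.36 ± 0.24. The p53 target genes were higher (camera, adjusted p = 2.06e-06, 6.74e-07 to 0.646 over the alternatives; adjusted p = 0.266 with an estimated correlation), with the cell cycle inhibitor gene CDKN1A at 0.73 ± 0.18. NF-kB and inflammatory genes were higher (camera, adjusted p = 0.000228, 4.95e-53 to 0.996 over the alternatives; adjusted p = 0.956 with an estimated correlation), with the chemokine gene CXCL3 at 0.75 ± 0.23. Dendritic and Langerhans cell markers were higher (camera, adjusted p = 0.0180, 2.04e-08 to 0.996 over the alternatives; adjusted p = 0.956 with an estimated correlation), with BATF3 at 1.01 ± 0.45. MYC and ribosome biogenesis genes were lower (camera, adjusted p = 1.28e-06, 4.09e-12 to 0.996 over the alternatives; adjusted p = 0.956 with an estimated correlation), with MYC at -0.36 ± 0.12. Stem and progenitor genes were lower (camera, adjusted p = 0.00265, 0.000135 to 0.996 over the alternatives; adjusted p = 0.882 with an estimated correlation), with HLF at -0.57 ± 0.14. None of these 7 genes was called by edgeR with or without the block. Over all settings their log2 values ran from -0.52 to 2.0 for EGR3, 0.24 to 2.26 for SLC7A11, 0.38 to 1.07 for CDKN1A, 0.24 to 1.30 for CXCL3, 0.72 to 1.20 for BATF3, -0.69 to -0.099 for MYC and -1.23 to 0.043 for HLF. Without the block the sign turned for EGR3 (-0.52 without PLASS 2) and HLF (0.043 without EV 1). EGR3 (0.0153), SLC7A11 (0.00159) and CDKN1A (0.00159) passed with the block without EV 1, as did SLC7A11 (0.000997) without PLASS 1. Other settings with the block called SLC7A11 and CDKN1A by DESeq2 and SLC7A11 with no filter. Unblocked, other settings called SLC7A11 with no filter. edgeR called 0 members of these 7 lists with or without the block. At an unadjusted p under 0.05 there were, with the block and without it, 10 and 3 immediate early, 8 and 1 stress response, 5 and 3 p53 target, 5 and 0 NF-kB, 0 and 0 dendritic, 2 and 0 MYC and 3 and 0 stem and progenitor genes. DESeq2 called 1 and 0 stress response and 1 and 0 p53 target genes and 0 of the other lists, and limma-voom 0 of all 7. With no filter edgeR called 1 and 3 immediate early and 2 and 2 stress response genes and 0 of the other lists. Adjusted over the list alone with the block, 3 immediate early genes were higher and 3 stress response genes were higher.

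In PLASS vs EV the call of immediate early genes was lost without EV 1 (0.494) and turned direction without PLASS 2 (0.00872) in the unblocked fit. The call of stress response genes was lost without PLASS 2 (0.209) in the unblocked fit. The call of NF-kB genes turned direction without PLASS 2 (0.428) or EV 1 (0.000756) in the unblocked fit, and turned direction without EV 1 (0.354) in the blocked fit. The call of dendritic markers was lost without PLASS 1 (0.995) or EV 1 (0.883) in the unblocked fit, and turned direction without PLASS 1 (0.566) or EV 1 (0.826) in the blocked fit. The call of MYC and ribosome genes was lost without PLASS 1 (0.695) and turned direction without EV 2 (0.305) in the unblocked fit, and was lost without EV 2 (0.410) in the blocked fit. The call of stem and progenitor genes was lost without PLASS 2 (0.652) or EV 1 (0.696) in the unblocked fit, and was lost without EV 1 (0.0848) in the blocked fit. In replicate 2, 16 of 21 immediate early, 13 of 22 NF-kB and 7 of 28 (1 lower) MYC and ribosome genes were higher and 10 of 21 (1 higher) stem and progenitor lower.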

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

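The tests of the genes around MECOM, of transcript length and of GC content were planned before their results were seen, and those of scaling, transcript shares, construct reads, depth and SMN copies were chosen only after the results were seen.

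Transcripts with no gene name entered no comparison, and of 114 tested with the replicate block 1 passed the threshold in PLDLS vs PLASS and 2 in PLDLS vs EV. NM_201563 was higher with PLDLS than with PLASS by log2 2.05 and than with EV by 2.01, and NM_001079809 was higher with PLDLS than with EV by 2.47. The smallest edgeR adjusted p among these transcripts was 0.00748 in PLDLS vs PLASS and 0.00329 in PLDLS vs EV.

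MECOM was higher with both peptide constructs than with EV. Scaling and depth are argued against by the lowest log2 fold change of PLASS vs EV over all settings, 1.65, and more transcription of the whole region by the median of the 12 other tested genes within 1 Mb, -0.0179 (SD 0.323). An even rise of all transcripts is argued against by NM_001366470, which took at least 19.6% of MECOM reads in EV and 0% in peptide libraries. The 3 transcripts picked for excess over EV held at least 94.1% of MECOM reads in each peptide library. Construct reads and a switch of endogenous transcripts cannot be told apart without the construct's sequence. A response of endogenous MECOM to the peptide constructs stays open and untested.

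For the genes that differed between PLDLS and PLASS with the block, 227 of 297 calls remained with every library thinned to the depth of the shallowest, which argues against the lower depth of PLDLS as the whole cause. The trend of fold change spanned log2 0.0816 on transcript length and 0.0872 on GC content, against a median size of 1.30 for the called genes, so neither accounts for the pattern. A response to the PLDLS peptide may account for it, as a hypothesis found and tested on the same libraries. The count of calls depended on the libraries kept, and differences between the cultures other than the replicate number stay open and untested.

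SMN1 and SMN2 moved in opposite directions between libraries. SMN2 was at 60.6 and 0 CPM in PLDLS replicates 1 and 2, 2.55 and 0 in PLASS and 62.2 and 46.8 in EV. SMN1 was at 0 and 65.3, 57.9 and 72.5, and 0 and 51.8 CPM. Their sum differed by at most log2 0.71 between any pair of libraries, which is consistent with reads given to one or the other near-identical copy, but the counts per gene do not show which copy a read came from, so this and a change of the genes themselves cannot be told apart. No biological explanation was tested.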

How the results depend on the processing

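PLASS 1 is PLASS replicate 1 and so on. The block combined with other choices, and thinning, were chosen only after the data were seen, and the cause of each difference below was not tested unless fewer libraries or genes enter by construction. Without the block nearly all named genes were not called, so that they stayed so without 1 library says nothing about stability. With the block, of 59 called genes named in PLDLS vs PLASS calls were lost for 28 without PLASS 1, 15 without PLASS 2, 31 without PLDLS 1, 27 without PLDLS 2, 0 without EV 1 and 0 without EV 2. In PLDLS vs EV, of 39 called genes named calls were lost for 3 without PLASS 1, 2 without PLASS 2, 9 without PLDLS 1, 9 without PLDLS 2, 0 without EV 1 and 1 without EV 2.

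In PLDLS vs PLASS, 0 genes were called, against 121 by DESeq2, 240 with no filter, 47 against the mean of PLASS and EV and 297 with the replicate block. With the block the count was 290 with DESeq2 size factors, 283 with upper-quartile scaling, 381 by DESeq2, 328 by limma-voom, 588 with no filter, 266 with the stricter filter, 306 with the length offset and 255 thinned. It was 94 without PLASS 1, 237 without PLASS 2, 149 without PLDLS 1, 145 without PLDLS 2, 1067 without EV 1 and 939 without EV 2. With the block it was also 1113 with only the 2 groups compared and 670 against the mean of both controls.

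In PLDLS vs EV, 2 genes were called, against 0 with upper-quartile scaling, 267 by DESeq2, 5 by limma-voom, 471 with no filter, 4 with the length offset, 5 thinned, 7 with only the 2 groups compared and 621 with the replicate block. Without 1 library it was 0 to 14. With the block the count was 603 with DESeq2 size factors, 599 with upper-quartile scaling, 708 by DESeq2, 732 by limma-voom, 1023 with no filter, 568 with the stricter filter, 675 with the length offset and 557 thinned. It was 697 without PLASS 1, 728 without PLASS 2, 283 without PLDLS 1, 332 without PLDLS 2, 2143 without EV 1 and 700 without EV 2, and 819 with only the 2 groups compared.

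In PLASS vs EV, 0 genes were called, against 3 by DESeq2, 33 with no filter and 2 with the replicate block. With the block the count was 2 with DESeq2 size factors, 2 with upper-quartile scaling, 24 by DESeq2, 1 by limma-voom, 37 with no filter, 2 with the stricter filter, 2 with the length offset and 1 thinned. It was 44 without PLASS 1, 10 without PLASS 2, 13 without PLDLS 1, 13 without PLDLS 2, 559 without EV 1 and 22 without EV 2, and 12 with only the 2 groups compared.

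For PLDLS vs PLASS and PLDLS vs EV, shared calls numbered 0, against 109 by DESeq2, 215 with no filter and 280 with the replicate block. With the block they were 272 with DESeq2 size factors, 263 with upper-quartile scaling, 338 by DESeq2, 312 by limma-voom, 508 with no filter, 251 with the stricter filter, 289 with the length offset and 233 thinned. They were 78 without PLASS 1, 225 without PLASS 2, 132 without PLDLS 1, 132 without PLDLS 2, 784 without EV 1 and 521 without EV 2.

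Gene lists that passed in PLDLS vs PLASS numbered 6 (1 up and 5 down), against 9 (3 up and 6 down) with the replicate block and 0 with an estimated correlation or fry, with or without the block. Without 1 library and without the block they were 12 (2 up and 10 down) without PLASS 1, 12 (8 up and 4 down) without PLASS 2, 9 (6 up and 3 down) without PLDLS 1, 7 (1 up and 6 down) without PLDLS 2, 6 (1 up and 5 down) without EV 1 and 6 (1 up and 5 down) without EV 2. With the block they were 11 (3 up and 8 down) without PLASS 1, 13 (7 up and 6 down) without PLASS 2, 12 (6 up and 6 down) without PLDLS 1, 10 (3 up and 7 down) without PLDLS 2, 11 (5 up and 6 down) without EV 1 and 11 (5 up and 6 down) without EV 2.

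In PLDLS vs EV they numbered 9 (4 up and 5 down), 13 (6 up and 7 down) with the replicate block, 7 (2 up and 5 down) with DESeq2 size factors and 0 with an estimated correlation or fry. Without 1 library and without the block they were 9 (4 up and 5 down) without PLASS 1, 11 (5 up and 6 down) without PLASS 2, 10 (7 up and 3 down) without PLDLS 1, 7 (1 up and 6 down) without PLDLS 2, 7 (1 up and 6 down) without EV 1 and 11 (6 up and 5 down) without EV 2. With the block they were 15 (8 up and 7 down) without PLASS 1, 14 (7 up and 7 down) without PLASS 2, 14 (8 up and 6 down) without PLDLS 1, 10 (5 up and 5 down) without PLDLS 2, 13 (7 up and 6 down) without EV 1 and 9 (3 up and 6 down) without EV 2.

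In PLASS vs EV they numbered 7 (5 up and 2 down), 7 (5 up and 2 down) with the replicate block and 0 with an estimated correlation or fry. Without 1 library and without the block they were 11 (9 up and 2 down) without PLASS 1, 13 (3 up and 10 down) without PLASS 2, 7 (5 up and 2 down) without PLDLS 1, 7 (5 up and 2 down) without PLDLS 2, 9 (4 up and 5 down) without EV 1 and 13 (10 up and 3 down) without EV 2. With the block they were 9 (5 up and 4 down) without PLASS 1, 8 (6 up and 2 down) without PLASS 2, 7 (5 up and 2 down) without PLDLS 1, 7 (5 up and 2 down) without PLDLS 2, 7 (5 up and 2 down) without EV 1 and 11 (6 up and 5 down) without EV 2.

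Signs of log2 fold changes turned for genes not called without the block, of which CD83 and ICAM1 in PLDLS vs PLASS and EGR3 in PLDLS vs EV passed with it. In PLDLS vs PLASS the range without 1 library was ADM -0.10 to 1.94 (-0.10 without PLASS 1 and -0.0092 without PLDLS 2), CD83 -2.28 to 0.053 (0.053 without PLASS 2), CLEC9A -1.73 to 0.012 (0.012 without PLASS 1), CTBP1 -0.22 to 0.078 (0.078 without PLASS 2 and 0.070 without PLDLS 1), CTBP2 -0.21 to 0.25 (-0.099 without PLASS 2 and -0.21 without PLDLS 1) and GATA2 -0.77 to 0.23 (0.23 without PLASS 2). It was ICAM1 -1.91 to 0.14 (0.14 without PLASS 2), MCM2 -0.81 to 0.0046 (0.0046 without PLASS 2 and 0.00059 without PLDLS 1) and PRG2 -2.15 to 0.76 (0.76 without PLASS 2 and 0.24 without PLDLS 1). Thinned, CTBP1 was at 0.018 (0.021 with the block) and CTBP2 at -0.015 (-0.019), and with the block CTBP2 was at -0.11 without PLDLS 1. In PLDLS vs EV the range was EGR3 -0.073 to 2.10 (-0.073 without PLDLS 2), and in PLASS vs EV CCL4 -1.86 to 3.45 (-1.86 without PLASS 2 and -0.26 without EV 1), EGR3 -0.52 to 2.0 (-0.52 without PLASS 2) and HLF -1.23 to 0.043 (0.043 without EV 1).

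Lists also turned, with adjusted p as follows. In PLDLS vs PLASS without 1 library the range was DNA replication genes 4.76e-15 to 0.760 (0.608 without PLDLS 1). In PLDLS vs EV it was MYC and ribosome biogenesis genes 3.33e-08 to 0.933 (0.933 without EV 2), immediate early genes 1.75e-06 to 0.895 (0.796 without PLDLS 2), NF-kB and inflammatory genes 1.69e-11 to 0.841 (5.13e-05 without EV 2) and cholesterol and fatty acid synthesis genes 4.74e-05 to 0.917 (0.576 without PLDLS 2 and 0.917 without EV 1). In PLASS vs EV it was MYC and ribosome biogenesis genes 4.09e-12 to 0.695 (0.305 without EV 2), NF-kB and inflammatory genes 2.61e-41 to 0.428 (0.428 without PLASS 2 and 0.000756 without EV 1) and immediate early genes 2.12e-38 to 0.494 (0.00872 without PLASS 2). With the block, NF-kB and inflammatory genes turned in PLDLS vs EV without PLDLS 2 (0.532) or EV 2 (0.210) and in PLASS vs EV without EV 1 (0.354), and dendritic and Langerhans cell markers in PLASS vs EV without PLASS 1 (0.566) or EV 1 (0.826).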

Other observations

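The tests between replicate numbers and of the S100A family were chosen only after the results were seen.

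Between replicate numbers, with the group as the other term, 1152 genes were higher and 1415 lower in replicate 2 than replicate 1 libraries, of 14631 tested (edgeR, adjusted p under 0.05). Within EV the number also parts different vectors, which the test cannot separate. Of the gene lists, 14 passed camera in this comparison with the preset correlation (adjusted p between 1.56e-19 and 0.0448) and none with an estimated one (between 0.433 and 0.618). Counting single genes that edgeR called higher in replicate 2, there were 16 of 21 immediate early genes (list median log2 1.14), among them the phosphatase gene DUSP1 (1.24 ± 0.16) and the nuclear receptor gene NR4A1 (0.94 ± 0.16), and 13 of 22 NF-kB and inflammatory genes (median 1.05), with CD83 (2.13 ± 0.19). Also called higher were 24 of 32 DNA replication genes (median 0.59), with MCM2 (0.66 ± 0.11), 15 of 24 cholesterol and fatty acid synthesis genes (median 0.50), with HMGCS1 (1.02 ± 0.12), 7 of 12 markers of mast cells, basophils and eosinophils (median 0.86), with HDC (1.01 ± 0.17), and 13 of 25 oxidative phosphorylation genes (median 0.45). Called lower were 9 of 25 G2/M and mitosis genes (median -0.36), with CCNB1 (-0.36 ± 0.10), 10 of 21 stem and progenitor genes, with 1 higher, and 3 of 10 lymphoid markers. Fewer were called higher of MYC and ribosome biogenesis (7 of 28, with 1 lower), hypoxia and glycolysis (7 of 26, with 2 lower), primary granule (3 of 8, with 1 lower) and reference genes (2 of 13). Among the 12 MHC class II genes edgeR called 0, with 8 at an unadjusted p under 0.05, DESeq2 3 and limma-voom 1. The members named were chosen after their values were seen.

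S100A genes, which encode calcium-binding proteins, were noticed among the genes higher with PLDLS than with PLASS. With the block S100A4 (1.29 ± 0.20), S100A6 (1.95 ± 0.33), S100A8 (1.96 ± 0.24), S100A9 (1.51 ± 0.18) and S100A11 (0.77 ± 0.15) passed, 5 of 8 tested members against 0.121 expected. Of 454 symbol families this was the 1 family past the threshold (Fisher's exact test, two-sided, adjusted p = 1.88e-05), which argues against chance if genes are independent, as neighbouring genes need not be. Of these 5, S100A8 (1.15 ± 0.19) and S100A9 (0.76 ± 0.15) were also higher in replicate 2. A shared response of this family may exist, as a hypothesis found and tested on the same libraries. Leaving out 1 library with the block ended calls without PLASS replicate 1 for S100A6 (0.0649) and S100A11 (0.460), without PLASS replicate 2 for S100A4 (0.0795), S100A6 (0.0589) and S100A11 (0.237), without PLDLS replicate 1 for S100A11 (0.295) and without PLDLS replicate 2 for S100A4 (0.0688), S100A6 (0.0855) and S100A11 (0.137). Other choices with the block ended calls after thinning for S100A6 (0.186) and S100A11 (0.0705).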
